A study of Homo sapiens with 6 samples.

How the data were processed

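RNA was sequenced in 6 libraries from OCI-AML2, an established human acute myeloid leukaemia cell line, after lentiviral delivery of a short hairpin RNA (shRNA) and selection in puromycin at 2.0 µg/ml for 3 days. The libraries were made with a directional (strand-keeping) kit, per the labels' protocols. The sample titles gave the groups: 2 control libraries, 2 with the ALR-directed shRNA coded 325 (sh325) and 2 with the one coded 456 (sh456), each pair lettered A and B. ALR is the protein encoded by GFER. The titles of the control libraries name GFP, whereas another label calls the hairpin scrambled, so the control hairpin is called control here.

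The submitters' processing notes name Trim Galore 0.4.0, TopHat2 2.0.11, HTSeq 0.6.1p2, edgeR 3.8.6, DESeq 1.18.0 and the genome build hg19. The role of each tool is not given in the sources used here. The authors deposited 6 tables of 13156 rows, each comparing 1 shRNA with both controls, with control A alone or with control B alone. Each table held RPKM (reads per kilobase of gene per 1e6 reads) for its libraries, per the file headers. It also held the authors' log2 fold change and a log2 mean abundance (logCPM), the test score LR, and a p-value with its false discovery rate (FDR), per the file headers. A library's RPKM values were identical in every table that listed it. After 2 repeated listings were dropped (CSNK1E and SFPQ, with equal values), 13154 gene symbols remained. No gene of the mitochondrial genome was listed. No coordinates are given, because the reference annotation in use here was of another build than hg19. That reference served only to match older and newer gene symbols, which added 5 of the fixed list symbols to those found directly.

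RPKM values are not counts, so the main test was limma 3.58.1 (R 4.3.3) with a mean-dependent prior (limma-trend) on log2(RPKM + 0.5). Genes needed an RPKM of at least 1 in at least 2 of the libraries fitted. Each shRNA was compared with control in a fit of its own 4 libraries, and sh325 with sh456 in a fit of all 6. A call was a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of genes with low RPKM. The labels do not say whether the A and B libraries came from separate infections, so the p-values measure only the spread between these samples, which may be technical.

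There were 28 gene lists fixed before the data were examined, with 825 distinct symbols. They covered the mitochondrial disulfide relay, complex IV, complex I, ATP synthase with complexes II and III, the mitochondrial genome, mitochondrial ribosome, mitochondrial protein quality, the TCA cycle, mature myeloid genes, primary granule genes, stem and progenitor genes, the cell cycle, ribosome biogenesis, cytosolic ribosome, the integrated stress response, oxidative stress, iron and iron-sulfur, copper and metallothionein, interferon, p53 targets, cholesterol synthesis, glycolysis and hypoxia, TNF and NF-kB, apoptosis regulators, replication histones, and markers of erythroid and megakaryocyte, lymphoid, and stromal and epithelial cells. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists tested. The test was repeated with a correlation estimated from the data and with fry, which asks whether a list's genes move on balance in one direction. The counts of members past the FDR in the authors' tables were added after the data were seen.

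The genes named follow a rule fixed before the data were examined. It takes GFER and COX17, then the 5 called genes with the largest rise and fall per shRNA among those with a mean RPKM of at least 2 in the higher group, then the 5 in each direction called under both shRNAs, then up to 4 called members per list, and the 3 in each direction with the largest difference between the shRNAs. Where a comparison had no call, the rank was by unadjusted p. Applying the same rule to the authors' deposited calls was decided after the data were seen.

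Depth was read from the RPKM steps. In 13153 of the 13154 genes (99.99%) the ratios between libraries resolved into whole reads, within 1e-07 of a whole number, and the RPKM rebuilt from them differed from the deposited values by at most 6.4e-12. The recovered reads over the listed genes came to between 18.5 and 20.3 per library in units of 1e6, with a median of 494 to 562 reads per gene. They made up 89.7% to 102% of the totals implied by the RPKM denominators, so those denominators were not the plain sum of the listed reads. The reads served for this check of depth and for limma's voom as an alternative chosen after seeing the data, with a minimum of 10 reads in at least 2 libraries.

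On simulated reads with the depth of these libraries and 1 spread per gene for all groups, 100 genes with a 2-fold and 100 with a 4-fold change were drawn 10 times per comparison. The main test called on average 66.9 and 96.7 of them for sh325 against control, 69.3 and 98.1 for sh456 against control, and 68.7 and 97.8 for sh325 against sh456. It called 15.9, 16.4 and 11.7 unchanged genes, respectively. A list of mature myeloid genes shifted by 0.3 on the log2 scale was called in 10 of 10 draws with the preset correlation and in 0 of 10 with the estimated one, for each shRNA. These simulations drew every library independently, without the shared deviation of libraries with the same letter described in the closing section. Genes were also drawn independently, whereas the correlation estimated under sh325 reached 0.877 (ATP synthase with complexes II and III). The list result thus cannot show whether the preset correlation suits these data. The control libraries varied more (log2 SD 0.329) than those of sh325 (0.249) and sh456 (0.196), so recovery against control may be lower than simulated.

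The alternatives were other pseudocounts and RPKM minimums, the replicate letter as a block, each library left out, median centring, quantile normalization, all 6 libraries in one fit, limma without a trend or with a robust prior, other thresholds, the authors' tables against a single control, and the voom fits. Leaving out a library was extended to every list, and to the lists between the hairpins, after the results were seen. Count models were not run as RPKM was the deposited unit. Because both shRNAs share the control libraries, 50 simulations of unchanged groups gave the overlap and the covariance of fold changes expected with no effect. They were first run with 1 spread for all groups. After the control libraries were seen to differ more (a log2 SD over genes of 0.329 in control, 0.249 under sh325 and 0.196 under sh456), 50 more were run with each group's own spread, and both versions are reported. Both drew every library independently of its letter. Figures were drawn with matplotlib 3.10.9.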

Results

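Gene expression was measured by RNA sequencing in OCI-AML2 cells carrying a control shRNA or the hairpins coded sh325 and sh456 here, with 2 libraries (A and B) per group. Both test hairpins target ALR, the sulfhydryl oxidase of the mitochondrial intermembrane space, which is encoded by GFER and reoxidises the import receptor of the mitochondrial disulfide relay. The series title names COX17, a copper chaperone for cytochrome c oxidase, and differentiation of the leukaemia cells as the outcomes of interest. Depth was similar across libraries, with recovered reads, in units of 1e6, of 18.9 and 20.3 in control A and B, 19.2 and 19.0 under sh325, and 19.95 and 18.5 under sh456. All values below are RPKM as deposited, given as mean ± SD of 2 libraries, or log2 fold changes on log2(RPKM + 0.5) ± SE.

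The first question was whether the hairpins lowered their target. GFER (Entrez 2671) stood at 4.90 and 7.58 RPKM in control A and B, 3.77 and 3.64 under sh325, and 0.950 and 0.957 under sh456. The mean was thus 59.4% of control under sh325 and 15.3% under sh456. With sh456 the fall passed the test (log2 fold change -2.18 ± 0.25, limma adjusted p = 0.0446), and the authors' deposited table gave -2.68 with an FDR of 6.90e-17. With sh325 the log2 fold change was -0.65 ± 0.24 (limma adjusted p = 0.451), and the authors' deposited table gave -0.71 with an FDR of 0.0579. Control A lay closer to the sh325 libraries than control B did. Without control A, the fall under sh325 passed the test (-0.94, limma adjusted p = 0.0379), and without control B it was smaller and not called (-0.36, limma adjusted p = 0.462). GFER was higher under sh325 than under sh456 by 1.53 ± 0.22 (limma adjusted p = 0.0256). COX17 (Entrez 10063) mRNA was 74.2 ± 16.5 RPKM in control, 67.6 ± 9.85 under sh325 and 70.9 ± 4.21 under sh456. Its log2 fold changes were -0.12 ± 0.21 (limma adjusted p = 0.929) and -0.05 ± 0.20 (limma adjusted p = 0.985), so no difference beyond the spread was detected at the level of mRNA.

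**Figure D1:**
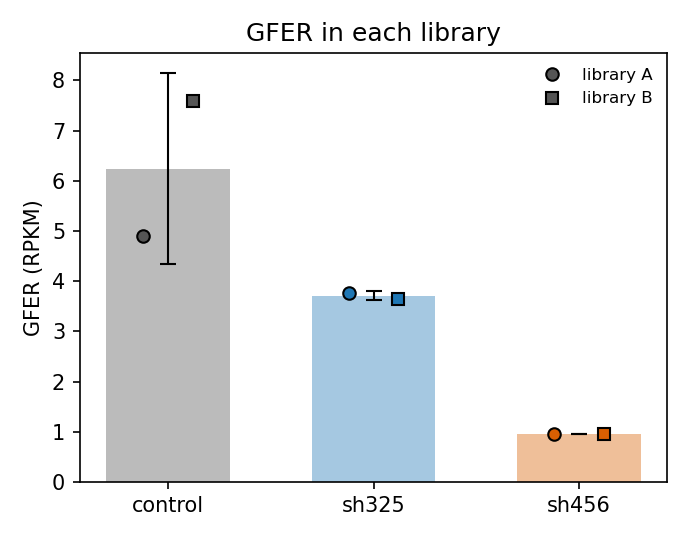
GFER in RPKM (vertical axis) in each library, with bars for the mean of the 2 libraries of a group, error bars for 1 SD, circles for library A and squares for library B. Both sh456 libraries sit at about 0.95 RPKM, and the control libraries differ from each other at 4.90 and 7.58 RPKM.

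Under sh325, no single gene passed the adjusted threshold, so genes were ranked by unadjusted p in each direction. TREM2, a receptor of macrophages and microglia, was 4.18 ± 0.19 RPKM in control and 22.0 ± 1.44 under sh325 (log2 fold change 2.26 ± 0.17, limma adjusted p = 0.0769). PTAFR, the receptor for platelet-activating factor, went from 2.15 ± 0.73 to 13.0 ± 1.78 RPKM (2.37 ± 0.25). The log2 fold changes were 3.08 ± 0.33 for PTGDS, a prostaglandin D synthase, 2.87 ± 0.32 for KCNH2, a potassium channel, and 1.66 ± 0.19 for SERPINB2, an inhibitor of plasminogen activators. The limma adjusted p was 0.116 for each of these last 4. On the lower side, CAPZA1, a subunit of the actin capping protein, was 198 ± 24.6 RPKM in control and 49.5 ± 0.14 under sh325 (-1.98 ± 0.16, limma adjusted p = 0.0769). The log2 fold changes of MPST, which transfers sulfur from mercaptopyruvate, VAT1L, GALNT3, which starts O-glycan chains, and UBE2E2, a ubiquitin-conjugating enzyme, were -1.86 ± 0.17, -1.72 ± 0.17, -1.79 ± 0.20 and -1.45 ± 0.17, with a limma adjusted p of 0.0855 for MPST and 0.116 for the other 3.

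limma called 0 of 10981 genes for sh325 against control, where 1095 had an unadjusted p under 0.05 (505 higher, 590 lower). The authors' deposited table held 1434 genes with an FDR under 0.05, of which 756 rose and 678 fell. The genes past that FDR were ranked by the authors' fold change among those with a mean RPKM of at least 2 in the higher group. Within this limit, PTGDS (4.38), KCNH2 (3.30), PTAFR (2.64), PRG3 (2.56), an eosinophil granule protein, and CCL2 (2.45), a monocyte chemokine, rose most. SNORD12C (-3.85), KRT81 (-3.31), MZB1 (-2.79), FAM46C (-2.62) and DACT3 (-2.57) fell most. With 1 library left out, which leaves 1 library in a group and assumes that it varies like the others, limma called 383 genes without control A, 361 without control B, 25 without sh325 A and 27 without sh325 B. A fit of all 6 libraries called 61, and whole reads with voom called 0 in the same 4 libraries and 66 in all 6. With the replicate letter as a block, limma called 520 in the same 4 libraries, although the labels do not say that the letters pair libraries.

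As groups, mature myeloid genes and p53 target genes were called higher under sh325, and cholesterol synthesis genes lower, with the preset correlation only. That test also called lists between the B and A libraries. Mature myeloid genes (camera adjusted p = 1.97e-04) and p53 targets (0.0249) were among them, but not cholesterol synthesis genes (0.803). A call with the preset correlation alone thus does not establish an effect of a hairpin. Of 56 mature myeloid genes in the tables, 17 rose, 6 fell and 33 did not pass the FDR in the authors' deposited table. The 47 tested in the RPKM fit had a median log2 fold change of 0.28 (camera adjusted p = 4.14e-04, and adjusted p = 0.906 with an estimated correlation). Among them, the authors' deposited table had rises in MS4A6A (log2 fold change 1.08) and CLEC7A (2.28), the beta-glucan receptor dectin, and falls in MMP9 (-2.35), a secreted gelatinase, and SAT1 (-1.11), which acetylates polyamines. Of 28 p53 target genes, 10 rose and 1 fell in the authors' deposited table, among them ZMAT3 (1.42), PHLDA3 (1.29), TP53INP1 (1.27) and the cell cycle inhibitor CDKN1A (1.11). The list's median was 0.29 over 26 tested genes (camera adjusted p = 2.38e-05, and adjusted p = 0.906 with an estimated correlation). Of 23 cholesterol synthesis and uptake genes, 8 fell and 0 rose in the authors' deposited table, including SQLE (-0.86), MSMO1 (-1.38) and INSIG1 (-0.95). Their median was -0.35 over 23 tested genes (camera adjusted p = 3.06e-07, and adjusted p = 0.906 with an estimated correlation). These 3 camera calls held without each library in turn, while the cholesterol synthesis median was -0.56 without control B and -0.27 without control A. Adjusted over the list alone, limma called 5 up and 2 down among mature myeloid genes, 5 up among p53 targets and 2 down among cholesterol synthesis genes.

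Further lists were called lower under sh325 with the preset correlation, and several of them rested on 1 control library. The 30 tested glycolysis and hypoxia genes had a median of -0.48 (camera adjusted p = 6.70e-06, and adjusted p = 0.906 with an estimated correlation), with 12 falls and 0 rises in the authors' deposited table, among them PDK1 (-1.19), ENO1 (-0.62) and LDHA (-0.68). Control A stood apart in this list, with a mean 0.80 above the 6-library level against -0.28 in control B. Without control A the median was -0.05 and the camera adjusted p 0.948. Cytosolic ribosomal protein genes had a median of -0.22 (camera adjusted p = 2.96e-10, and adjusted p = 0.906 with an estimated correlation), with falls of RPS10 and RPL35 and no other member in the authors' deposited table. Quantile normalization brought that median to 0.00 and ended the call (camera adjusted p = 0.978). Ribosome biogenesis genes (median -0.24, camera adjusted p = 1.57e-05), mitochondrial ribosome genes (-0.17, 0.00233), mitochondrial protein quality genes (-0.24, 0.00165), ATP synthase with complexes II and III (-0.15, 0.0294), complex IV (-0.11, 0.0463) and the TCA cycle (-0.16, 0.0463) also fell. With an estimated correlation the adjusted p was 0.906 for each. Control B stood highest of the 6 libraries in all 6 of these lists, and without it the adjusted p was 0.693, 0.985, 0.243, 0.957, 0.980 and 0.926 in the same order, with medians between -0.11 and 0.08. Without sh325 A, the last 5 of these calls also ended (0.357, 0.0898, 0.792, 0.599 and 0.739). Quantile normalization ended those of the mitochondrial ribosome (0.0613), ATP synthase with complexes II and III (0.558), complex IV (0.558) and the TCA cycle (0.35), and a minimum RPKM of 5 ended the last 3 (0.0938, 0.115 and 0.115). The replication histone list was called higher (median 0.60 over 11 genes, camera adjusted p = 0.00531, and adjusted p = 0.906 with an estimated correlation). Its median was 0.37 without control B, and a minimum RPKM of 5 ended the call (camera adjusted p = 0.937). The TCA cycle call also ended with voom on whole reads (0.0520). Adjusted over the list alone, limma called 0 genes in the lists of this paragraph.

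With sh456, CEACAM6 had the largest rise and GFER the largest fall among the genes called. CEACAM6, an adhesion molecule of granulocytes, was 26.6 ± 1.06 RPKM in control and 157 ± 16.2 under sh456 (log2 fold change 2.54 ± 0.17, limma adjusted p = 0.0202). TGM5 (2.52 ± 0.19), TGM3 (2.49 ± 0.27), PTAFR (2.33 ± 0.27) and SERPINB2 (2.18 ± 0.19) were the other genes with the largest rises. NOB1, an endonuclease that matures the small ribosomal subunit, fell from 66.0 ± 11.5 to 17.9 ± 1.92 RPKM (-1.85 ± 0.19, limma adjusted p = 0.0435). IGFBP4 (-1.74 ± 0.20), which binds insulin-like growth factors, HERC5 (-1.73 ± 0.20), the ligase for the interferon-induced modifier ISG15, and MED11 (-1.65 ± 0.17), a Mediator subunit, also fell. By rank of fold change in the authors' deposited table, MMP8 (2.85), ITGB2-AS1 (2.93) and RASD1 (2.59) were among the top rises, and IFI27 (-4.40), OAS3 (-2.67), AXL (-2.53) and CERCAM (-2.51) among the top falls. ITGB2-AS1 overlaps ITGB2 on the other strand and can be told from it only if the counting used strand, which is not given in the sources used here. IFI27 was 158 RPKM in control A and 21.0 in control B, against 4.36 and 2.16 under sh456.

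limma called 17 of 10926 genes for sh456 against control (10 rose and 7 fell), and all 17 were among the 1115 genes (629 up, 486 down) past an FDR of 0.05 in the authors' deposited table. At an unadjusted p under 0.05 there were 1044. The count was 1 with no RPKM minimum, 41 with a minimum of 5, 2 after median centring or quantile normalization, 8 without a trend, 63 with all 6 libraries in one fit and 33 with voom on whole reads. With the replicate letter as a block, a pairing that the labels do not give, it was 584. After median centring or quantile normalization, and with pseudocount 1, no minimum or no trend, the call of GFER itself ended (limma adjusted p between 0.0503 and 0.0963) with log2 fold changes between -1.87 and -2.22. CEACAM6 kept its call in each alternative run. With 1 library left out, limma called 647 genes without control A, 603 without control B, 33 without sh456 A and 29 without sh456 B.

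As groups, mature myeloid genes were called higher and interferon-stimulated genes lower under sh456, with the preset correlation only. That test also called both lists between the B and A libraries (camera adjusted p = 1.97e-04 and 0.00106). Of the 56 mature myeloid genes, 21 rose and 0 fell in the authors' deposited table, among them S100A8 (1.66), S100A9 (1.58) and S100A12 (2.46), the calcium-binding proteins abundant in neutrophils and monocytes, and TLR8 (1.75), an endosomal RNA receptor. The median was 0.35 over 46 tested genes (camera adjusted p = 4.37e-10, and adjusted p = 0.918 with an estimated correlation). Without control B it was 0.16 and still called (adjusted p = 2.80e-04). Of 39 interferon-stimulated genes, 24 fell and 0 rose in the authors' deposited table, among them IFI27, HERC5, OAS3 and IFI6 (-1.81). Their median was -0.99 over 35 tested genes (camera adjusted p = 1.65e-16, and adjusted p = 0.918 with an estimated correlation). Control A stood above every other library in this list, with a mean of 0.84 against -0.10 in control B, 0.15 and 0.26 under sh325, and -0.56 and -0.60 under sh456. Without control A the median was -0.30 and without control B -1.40, and both were called (adjusted p = 2.10e-04 and 5.78e-30). Adjusted over the list alone, limma called 9 up among mature myeloid genes and 16 down among interferon genes.

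Under sh456, 6 further lists passed the same test. Replication histones (median 0.55, camera adjusted p = 0.00235) and stem and progenitor genes (0.29, 0.0160) rose, and ribosome biogenesis (-0.19, 0.00190), mitochondrial ribosome (-0.13, 0.0160), mitochondrial protein quality (-0.19, 0.0347) and glycolysis and hypoxia genes (-0.19, 0.0250) fell. With an estimated correlation the adjusted p was 0.918 for each. In the stem and progenitor list, MMRN1 (1.15), SPINK2 (1.77) and EMP1 (1.49) rose and MYC (-0.51) fell in the authors' deposited table. Without control B the adjusted p was 0.165, 0.279, 0.711, 0.711 and 0.673 for the first 5 in this order, and the medians of ribosome biogenesis (0.08) and mitochondrial ribosome (0.02) turned. Without control A, which stood apart in the glycolysis and hypoxia list, that list's median was 0.17 with a call in the other direction (adjusted p = 0.0137). The mitochondrial protein quality call also ended without sh456 A or B (0.231 and 0.108), the mitochondrial ribosome call without sh456 A (0.231) and the glycolysis and hypoxia call without sh456 B (0.186). A minimum RPKM of 5 ended the stem and progenitor call (0.123), and no minimum (0.0600) or voom on whole reads (0.0512) ended the glycolysis and hypoxia call. Adjusted over the list alone, limma called 3 stem and progenitor genes and 1 replication histone gene up, and 0 in the other 4 lists.

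**Figure D2:**
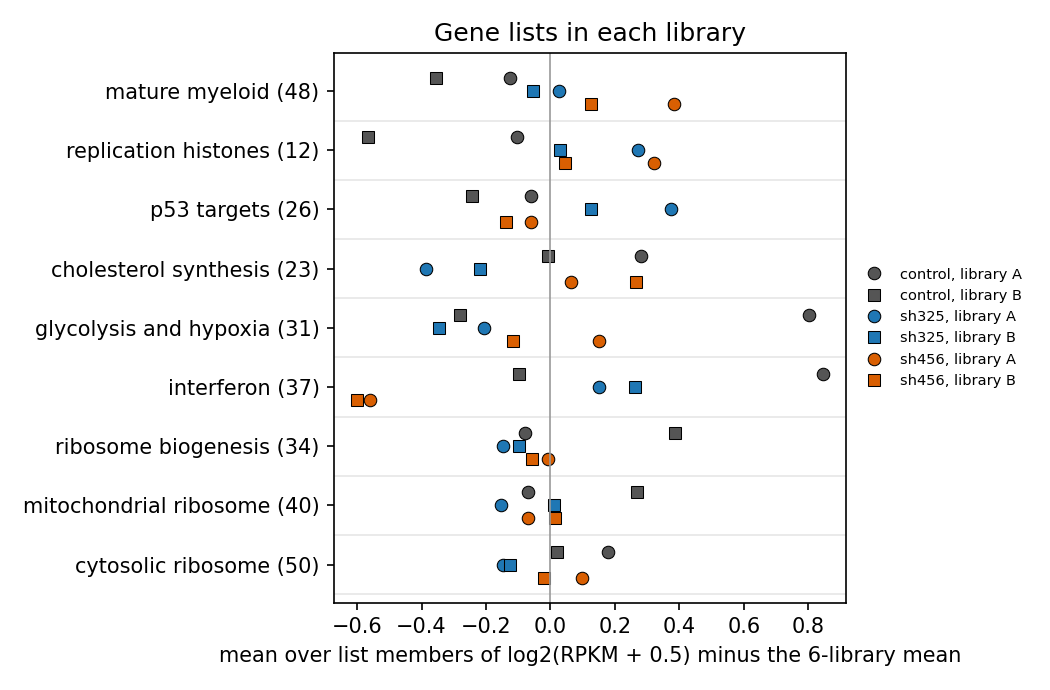
Mean over the members of each gene list of log2(RPKM + 0.5) relative to the 6-library mean (horizontal axis), for 9 lists (rows, with the number of genes), with colours for the groups, circles for library A and squares for library B. Control A stands apart in the interferon (0.84) and glycolysis and hypoxia (0.80) lists, and both sh456 libraries lie lowest in the interferon list (-0.56 and -0.60).

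The next question was which genes changed under both hairpins. PTAFR and SERPINB2, named above, were higher in all 4 shRNA libraries than in either control. So were CXCR2, a chemokine receptor of neutrophils (5.33 ± 0.25 RPKM in control, 12.2 ± 0.18 and 16.5 ± 0.38 under sh325 and sh456), CLDND1 (log2 fold changes 1.37 and 1.54) and ARHGAP19 (1.24 and 1.37). PRTN3, a serine protease of primary granules, was lower under both (130 ± 23.5, 48.0 ± 5.16 and 54.1 ± 0.22 RPKM), as were LYRM5 (-0.81 and -0.98), TMED7 (-0.86 and -1.38), ZNF138 (-0.93 and -0.87) and SFXN3 (-0.76 and -1.18), a mitochondrial carrier. In the authors' deposited tables, CCL2 (2.45 and 2.07), CCL23 (1.86 and 1.93) and LOC93432 (1.87 and 1.90) were among the genes with the largest rises under both, and OTOF (-1.81 and -2.19), OASL (-1.32 and -1.99), PPARG (-1.50 and -1.31) and MPO (-1.68 and -1.24), the myeloperoxidase of primary granules, among the falls. OTOF stood at 4.05 RPKM in control A and 0.702 in control B, and the shRNA libraries lay between 0.383 and 0.572.

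limma called 0 genes in the same direction under both shRNAs. With the replicate letter as a block it called 98, although the labels do not say that the letters pair libraries. At an unadjusted p under 0.05, 166 genes were higher and 76 lower under both among 10823 tested in both, where independent lists of these sizes would share 23.6 and 25.3. The authors' deposited tables shared 198 rises and 79 falls, where independent lists would share 36.2 and 25.1, and 62 genes went in opposite directions (60.4 for independent lists). Because the controls are shared, unchanged groups were simulated against them. With 1 spread for all groups they shared an average of 60.5 higher and 65.8 lower genes at an unadjusted p under 0.05, and with each group's own spread 97.1 and 108, against 169 and 77 observed over the same 11123 genes. The highest draw had 77 higher genes with 1 spread and 122 with each group's own, both below the observed 169. The lower genes ranged over the draws from 43 to 84 and from 88 to 146, respectively. The fold changes correlated across genes, which are not independent replicates, at 0.317, below the 0.502 and 0.685 of these simulations. Their covariance was 0.0372 against 0.0251 and 0.0388, so the sign of the difference (0.0121 or -0.00162) depended on the spread assumed for the controls. The simulations had an average of 3.04 and 0.56 genes in opposite directions (at most 9 and 2), against 36 observed. From same-letter differences with no library in common, the covariance shared by the hairpins was 0.000217 (95% resampling interval over genes -0.00318 to 0.00420), and over all pairs of libraries it was -0.0308 (-0.0352 to -0.0266). The second value includes pairs of unlike letter, which the shared deviation of same-letter libraries pulls down. It therefore cannot show what the hairpins share. The shared rises thus exceeded every draw of both simulations, while the 77 shared falls lay below every draw with each group's own spread. The simulated libraries were independent of letter, and their fold changes correlated more than those observed. The simulations therefore cannot decide how much of the shared rises or falls comes from the shared controls. The shared count was 9 with all 6 libraries in one fit, 10 with voom on them, 123 without control A and 144 without control B.

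**Figure D3:**
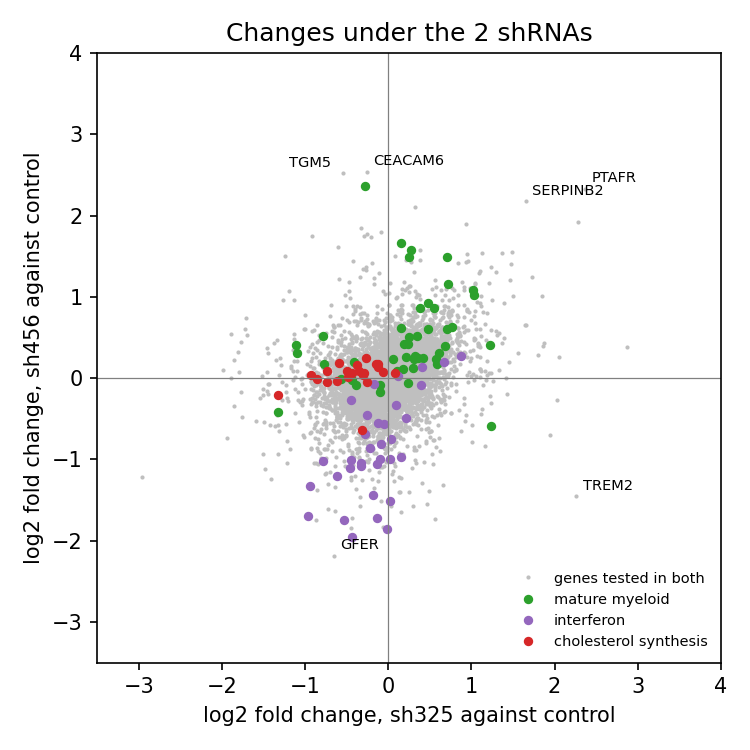
Log2 fold change against control on the log2(RPKM + 0.5) scale under sh325 (horizontal axis) and sh456 (vertical axis) for 10823 genes (grey), with mature myeloid, interferon and cholesterol synthesis genes in colour; 1 gene lies outside the axes. Interferon genes lie low on the vertical axis (median -0.99) and cholesterol synthesis genes low on the horizontal axis (median -0.35).

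The hairpins also differed from each other. TREM2 was higher under sh325 than under sh456 by 3.71 ± 0.16 on the log2 scale (limma adjusted p = 9.17e-04), as were KCNH2 (2.50 ± 0.31) and PTGDS (2.36 ± 0.35). TGM5 (-3.06 ± 0.18), CEACAM6 (-2.80 ± 0.18) and CHI3L1 (-2.74 ± 0.33), a chitinase-like secreted protein, were lower under sh325. CHI3L1 was 15.9 ± 7.67 RPKM in control, 6.16 ± 1.52 under sh325 and 43.5 ± 5.07 under sh456. CAPZA1 (-2.09 ± 0.14), MPST (-1.51 ± 0.14), VAT1L (-2.32 ± 0.15), NOB1 (1.40 ± 0.17) and MED11 (1.80 ± 0.16) were also called. limma called 245 of 11123 genes (72 higher and 173 lower under sh325), where 1803 had an unadjusted p under 0.05. With the replicate letter as a block, a pairing that the labels do not give, it called 818. Leaving out a shRNA library reduced the count to 15 (sh325 A), 6 (sh325 B), 1 (sh456 A) or 1 (sh456 B), while it was 679 without control A, 679 without control B and 665 with the 4 shRNA libraries alone. TREM2 kept its call without each library in turn (adjusted p between 0.00181 and 0.0223). The calls of TGM5 and CEACAM6 ended without sh456 A (0.0710 for both) or B (0.0835 for both), and those of KCNH2, PTGDS and CHI3L1 without any 1 of the 4 shRNA libraries (0.0644 to 0.215). Between the hairpins, interferon genes (median difference 0.70) and p53 targets (0.21) were higher under sh325, and cholesterol synthesis (-0.49), cytosolic ribosome (-0.16) and mature myeloid genes (-0.14) were lower (camera adjusted p = 6.09e-11, 0.00198, 5.06e-07, 9.43e-05 and 0.0499). With an estimated correlation the adjusted p was 0.909 for each. Adjusted over the list alone, limma called 9 interferon and 5 p53 target genes higher, and 10 cholesterol synthesis genes lower under sh325, and 1 mature myeloid gene higher and 9 lower. The interferon, p53 target and cholesterol synthesis calls held without each library in turn. The size of the p53 target difference depended on the library. The list's mean relative to the 6-library level was 0.37 in sh325 A and 0.12 in sh325 B, against -0.06 and -0.14 in sh456 A and B. The cytosolic ribosome call ended without sh456 A (0.0685), and the mature myeloid call without control A (0.0651), control B (0.0660), sh325 B (0.0600) or sh456 A (0.322). Calls also appeared in other lists when a library was left out, most often for glycolysis and hypoxia genes, called lower under sh325 without control A (0.00657), control B (0.00369) or sh456 B (0.00212).

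Genes of the disulfide relay, a list that counts the target GFER itself with substrates and partners of ALR, passed no list test with all libraries. Their median was -0.13 under sh325 (camera adjusted p = 0.0551) and -0.06 under sh456 (0.179). Both depended on the controls. Without control A the list was called downwards under both hairpins (-0.34, adjusted p = 1.53e-04, and -0.22, 0.00324), and without control B the medians were 0.02 and 0.12 with no call. Under sh325 it was also called downwards without sh325 B (-0.27, 0.0408). CHCHD3, a subunit of the complex that holds the inner membrane folds, was 39.3 ± 8.65 RPKM in control and rose under both hairpins in the authors' deposited tables (0.94 and 1.14), while COA4 (-0.68) and COA5 (-0.56) fell under sh325 in the authors' deposited table. Complex I genes had medians of -0.07 and -0.03 (camera adjusted p = 0.269 and 0.615 for sh325 and sh456), and complex IV, ATP synthase with complexes II and III and the TCA cycle were at -0.04, -0.06 and -0.06 under sh456 (0.530, 0.525 and 0.525). Without control A these 3 were called downwards (adjusted p = 0.0175, 0.00341 and 0.0272), as was complex I under both hairpins (0.00101 and 0.00519), and complex I under sh325 also without sh325 B (0.0408). No tested list of other blood lineages passed the threshold with all libraries. The erythroid and megakaryocyte list had 3 tested genes (medians -0.06 and 0.23, camera adjusted p = 0.661 and 0.0849) and the lymphoid list 4 (-0.18 and -0.12, 0.932 and 0.577). Under sh325 the means of these 2 lists had the opposite sign (0.07 and 0.16), which the test followed. Under sh456 the erythroid and megakaryocyte list was called upwards without control A (adjusted p = 0.0121) or sh456 B (0.0122). The stromal and epithelial list had 1 tested gene and the mitochondrial genome list none, so neither was tested.

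Of the lists fixed for stress and metabolism, those not named above passed no test under either hairpin with all libraries, although single members did in the authors' deposited tables. In the oxidative stress list (medians 0.04 and 0.01 under sh325 and sh456, mean -0.01 under sh456, camera adjusted p = 0.216 and 0.787), 8 genes rose and 1 fell under sh325 and 5 rose and 3 fell under sh456 in the authors' deposited tables. Under sh325 that list was called upwards without control B (camera adjusted p = 0.0251) or sh325 A (0.00185). SLC7A11, the cystine carrier, rose under both (1.20 and 0.68 in the authors' deposited tables), and FTH1, the ferritin heavy chain, fell under sh456 (-1.42 in the authors' deposited table). The integrated stress response list stood at -0.16 and -0.12 (camera adjusted p = 0.216 and 0.0834), iron and iron-sulfur genes at -0.09 and -0.06 (0.509 and 0.396), and copper and metallothionein genes at 0.00 and -0.01, with means of 0.11 and 0.01 (0.339 and 0.760). The integrated stress response list was called downwards without control B under both hairpins (0.0450 and 0.0164) and, under sh456, without sh456 B (0.0227). SLC31A1, the copper importer of the plasma membrane, was 12.3 ± 0.49 RPKM in control and fell under sh325 in the authors' deposited table (-0.94). The TNF and NF-kB list was at -0.25 and 0.13 (camera adjusted p = 0.0564 and 0.722), with 8 falls and 3 rises under sh325 in the authors' deposited table, among them CXCL8 (-1.81) and TNF (-1.08). It was called downwards under sh325 without control B (0.00350) or sh325 B (0.00488). Apoptosis regulators stood at -0.02 and 0.11 (0.852 and 0.366), and BCL2 (-0.70) fell under sh325 in the authors' deposited table.

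Primary granule genes went in both directions. Their medians were 0.02 and 0.31 under sh325 and sh456, with means of -0.12 and 0.13 (camera adjusted p = 0.339 and 0.275), and 1 rose and 4 fell under sh325, and 5 rose and 3 fell under sh456, in the authors' deposited tables. Under sh325 the list was called downwards without control B (-0.37, camera adjusted p = 0.0217) or sh325 A (-0.30, 0.0170), and under sh456 it was called upwards without control A (0.53, 0.00769). PRTN3 and MPO fell and SERPINB10 (1.60 and 1.51) rose under both in the authors' deposited tables. Stem and progenitor genes had a median of -0.06 and a mean of 0.08 under sh325 (camera adjusted p = 0.852), where GATA2, a transcription factor of progenitors, rose (1.98) and MYC (-0.61) and FLT3 (-0.57) fell in the authors' deposited table. Cell cycle genes were at -0.07 and -0.08 (camera adjusted p = 0.509 and 0.245), with the controls opposed in this list. Without control A it was called downwards (-0.35, adjusted p = 8.23e-06, and -0.33, 5.01e-07), and without control B upwards (0.21, 0.00394, and 0.16, 0.0192). It was also called downwards without sh325 B (-0.19, 0.0189) and without sh456 B (-0.20, 0.0122). The interferon list had a median of -0.14 under sh325 (camera adjusted p = 0.269) that followed the control used. Without control A it was 0.22 with a call upwards (7.92e-05), and without control B it was -0.65 with a call downwards (5.49e-11). It was also called downwards without sh325 B (-0.18, adjusted p = 0.0406). Under sh456, p53 targets (median 0.08, camera adjusted p = 0.650), cholesterol synthesis genes (0.06, 0.615) and cytosolic ribosome genes (-0.08, 0.179) passed no test. Without control A the cholesterol synthesis list was called upwards (0.20, adjusted p = 0.0193), and the cytosolic ribosome list was called downwards without control B (-0.14, 0.0159) or sh456 A (-0.13, 0.0352).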

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

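The tests of the interferon pattern below were chosen after its values had been seen. The hairpins differed from each other by a test of the difference itself in 245 genes of the 6-library fit. The log2 difference (sh325 minus sh456) was 3.71 for TREM2, 2.50 for KCNH2, 2.36 for PTGDS, -3.06 for TGM5, -2.80 for CEACAM6 and -2.74 for CHI3L1. By the same kind of test the lists differed by a median of 0.70 (interferon), 0.21 (p53 targets), -0.49 (cholesterol synthesis), -0.16 (cytosolic ribosome) and -0.14 (mature myeloid). With an estimated correlation none of these 5 lists was called (adjusted p = 0.909 each). With the preset correlation, the last of these calls ended without either control, sh325 B or sh456 A. The p53 target difference was larger in sh325 A, with a list mean of 0.37 relative to the 6-library level, than in sh325 B (0.12). Both hairpins target GFER, and each is represented by 2 libraries, and other transcripts bound by either hairpin were not tested. Changes in proportion to the loss of GFER, as the source of all effects, are argued against by the slope of effects under sh456 on those under sh325. It was 0.00304 (95% resampling interval over genes -0.0466 to 0.0554) from same-letter differences. Over all pairs of libraries it was -0.835 (-1.09 to -0.631). The shared deviation of same-letter libraries pulls this second value down, so it cannot decide the question. Effects of sh325 alone would lower the slope, so it cannot exclude proportional changes in some genes. Both slopes can be biased, because libraries of a letter deviate together.

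Interferon-stimulated genes were lower under sh456, in a list where control A stood far above control B. The call was lost with an estimated correlation (0.787 in this list, adjusted p = 0.918) and with fry (0.797). In the comparison that leaves the controls out, the list was lower under sh456 than under sh325. The median of sh456 minus sh325 was -0.643 between the A libraries (95% resampling interval over members -0.749 to -0.447) and -0.764 between the B libraries. This comparison cannot tell a fall under sh456 from a rise under sh325, so it does not test the fall against control. Each value compares 1 library with 1, and the members were correlated (0.687 estimated between the hairpins). The interval thus does not measure the spread between libraries, and the difference between the hairpins rests on the same direction in both letters. A single deviant sh456 library is argued against, since each lay below the mean of the other 4 libraries, by a median of -0.842 (A) and -0.737 (B). Against the control of the same letter, sh456 gave -1.35 (A) and -0.566 (B), so the size of its fall, but not the direction, depended on the control. For sh325 the values were -0.731 (A) and 0.313 (B), so the direction for that hairpin is open. Whether the list follows the deeper loss of GFER, at 0.257 of the level under sh325, cannot be told apart from a property of the hairpin, because there is 1 hairpin at each level.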

How the results depend on the processing

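Counts of called genes depended strongly on the libraries and the fit, whereas the direction of GFER and of the mature myeloid list did not change in any alternative run. With 1 library left out, the remaining library of that group is assumed to vary like the others. The range was then 25 to 383 genes for sh325, 29 to 647 for sh456, 1 to 679 between the hairpins and 0 to 144 under both. GFER ranged from -0.94 (called, without control A) to -0.36 under sh325 and from -2.19 to -2.18 under sh456, where leaving out a control gave no value because GFER then missed the RPKM minimum, as it did with a minimum of 5. The lists past the threshold ranged from 9 to 17 and from 6 to 17, and the mature myeloid adjusted p from 6.09e-06 to 0.0450 and from 4.09e-20 to 2.80e-04, for sh325 and sh456. The cause of these shifts was not tested. The count models planned for counts were not run, since RPKM was deposited. Depth was similar across libraries, and low genes rest on few reads.

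For sh325 against control, the count was 3 with a minimum RPKM of 5, 8 with quantile normalization, 61 with all 6 libraries and 66 with voom on them. For sh456 it was 1 with no minimum, 41 with a minimum of 5, 2 with median centring, 2 with quantile normalization, 63 with all 6 libraries, 8 without a trend, 33 with voom and 78 with voom on all 6. Between the hairpins it was 665 with the 4 shRNA libraries alone. Under both it was 9 with all 6 libraries, 10 with voom on them and 242 at an unadjusted p under 0.05. The voom fits and those of all 6 libraries with a block were chosen after seeing the data. The call of GFER under sh456 ended with pseudocount 1 (-1.87), no minimum (-2.18), median centring (-2.21), quantile normalization (-2.22) and no trend (-2.18). In the authors' deposited tables, the count was 3348 against control A only and 2554 against control B only for sh325, and 2592 and 2359 for sh456. With an estimated correlation 0 lists were called for either hairpin and the mature myeloid adjusted p was 0.906 and 0.918. With fry 0 lists were called and it was 0.619 and 0.797. In simulated data with independent libraries and independent genes the estimated correlation missed a shift of 0.3 in the mature myeloid list in 10 of 10 draws, and no other list was simulated. Because the simulated genes were independent, this does not show that the preset correlation suits these data.

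The replicate letter as a block moved the counts to 520 (sh325), 584 (sh456), 818 (between hairpins) and 98 (both). With all 6 libraries and the block they were 445, 291 and 68 for the first, second and last, and with voom in addition 787, 463, 1255 and 118. The labels do not say that the letters pair libraries, and 2 letters are too few to establish it, although same-letter deviations correlated at 0.418 to 0.569 between groups. The block ended the mitochondrial protein quality call under sh456 (0.0719) but changed no call of GFER or of the mature myeloid list.

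Some directions turned (for lists, that of the test), given here as adjusted p for lists and log2 fold change for genes. With a minimum RPKM of 5 under sh325, these were replication histones (0.937) and interferon (0.864), and with the block, stem and progenitor genes (0.978). Without control A they were stem and progenitor (0.576) and interferon genes (7.92e-05) under sh325, and glycolysis and hypoxia (0.0137), cytosolic ribosome (0.691) and SLC2A3 (0.0937) under sh456. Without control B they were COX17 (0.10), complex IV (0.980) and ATP synthase with complexes II and III (0.957) under sh325. Under sh456 they were COX17 (0.18), BTG2 (-0.24), complex IV (0.422), ATP synthase with complexes II and III (0.196), mitochondrial ribosome (0.711), ribosome biogenesis (0.711), p53 targets (0.764), cholesterol synthesis (0.196) and the TCA cycle (0.581). Without sh325 A, COX17 (0.02) and stem and progenitor genes (0.510) turned, and without sh325 B the latter (0.934). Without sh456 A, complex IV, ATP synthase with complexes II and III and the TCA cycle turned (0.934 each), and without sh456 B, COX17 (0.01) and cholesterol synthesis (0.417). The same results without another library were, under sh325, COX17 -0.35, complex IV 3.46e-04 and ATP synthase with complexes II and III 2.42e-05 without control A, and interferon 5.49e-11 without control B. Under sh456 they were BTG2 1.95, COX17 -0.28, complex IV 0.0175, ATP synthase with complexes II and III 0.00341, mitochondrial ribosome 1.53e-06, ribosome biogenesis 6.24e-10, p53 targets 0.129, cholesterol synthesis 0.0193 and the TCA cycle 0.0272 without control A. They were SLC2A3 -1.93, glycolysis and hypoxia 3.25e-15 and cytosolic ribosome 0.0159 without control B, and glycolysis and hypoxia 0.186 and cytosolic ribosome 0.919 without sh456 B. The cause was not tested. Of the other list alternatives, 420 kept direction and side of the threshold, 69 missed it and 8 newly passed it, and for the genes named the numbers were 1848, 56 and 486.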

Other observations

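The tests on letters and on response size were written down before their results, except that the version over all pairs of libraries was added after the first values were seen. Libraries with the same letter deviated together. Across 11123 genes, which are not independent replicates, the difference between A and B correlated at 0.418 between control and sh325, 0.432 between control and sh456, and 0.569 between the hairpins. With library B against A as the contrast, cell cycle genes were higher in the B libraries (median 0.32, camera adjusted p = 2.84e-11), as were ATP synthase with complexes II and III (0.24, 3.29e-06) and complex I genes (0.20, 6.42e-05). Glycolysis and hypoxia genes (-0.37, 8.94e-06), replication histones (-0.48, 0.00268), interferon genes (-0.22, 0.00106), mature myeloid genes (-0.12, 1.97e-04), primary granule genes (-0.28, 4.05e-04) and p53 targets (-0.14, 0.0249) were lower there. limma called 1 gene by letter, so list calls with the preset correlation arose between letters almost without single genes called. Gene length bias is argued against, since the lowest of the 3 correlations was 0.428 (95% resampling interval 0.406 to 0.443) after a trend on length was removed. After quantile normalization it was 0.361 (0.340 to 0.384). A single scale factor per library shifts all genes nearly alike on the log2 scale and hardly changes these correlations. The second result thus speaks only to differences between libraries in the distribution of values. What the letters stand for is not given in the labels, and no biological explanation was tested.

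GFER fell further under sh456, and the size of the response was compared with this. A response under sh456 at least 1.5 times as large in variance was not seen. The ratio of effect variances (sh456 over sh325), from same-letter differences, was 0.948 (95% resampling interval over genes 0.843 to 1.07), and 1.07 (0.871 to 1.34) over all pairs of libraries. These intervals, like those of the slope below, resample genes that are not independent and do not measure the spread between libraries. Noise hiding a larger response thus cannot be excluded. Changes in proportion to the loss of GFER mRNA, as the source of all effects, are argued against by the slope of effects under sh456 on those under sh325, at 0.00304 (-0.0466 to 0.0554), where a value above 1 was needed. Effects of sh325 alone would lower this slope, so it cannot exclude proportional changes in some genes. Over all pairs the slope was -0.835 (-1.09 to -0.631), which the shared deviation of same-letter libraries pulls down, so that value cannot decide the question. Because libraries of a letter deviate together, neither version rests on independent libraries, and both slopes can be biased by this. Protein levels are not in the files, so protein that does not follow the mRNA stays open.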
